A study of Drosophila melanogaster with 18 samples.

How the data were processed

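Total RNA from sorted Drosophila S2 cells was measured on 18 one-colour Agilent arrays, 3 for each combination of 3 double-stranded RNAs (GFP, Relish, Akirin) and 2 vectors (empty and PGRP-LCa). Per the labels' protocols, 2e+06 cells were transfected by calcium phosphate with 5 µg of double-stranded RNA and 1 µg of each plasmid, Tomato-positive cells were sorted after 48 h, and 200 ng of RNA with an integrity number above 6.5 was used per array. The deposited scanner files hold fluorescence intensity values that, per the file headers, were extracted with Agilent Feature Extraction 10.7.3.1 under its 1-colour protocol, with background subtraction but no normalization between arrays. Probe positions are those of the dm3 build that the files name. The deposited series matrix holds 32161 probes with column medians from 266 to 270, and each of its 18 columns correlated best with its own array, with r between 0.976 and 0.999 across probes on the log2 scale. Its values lie on a linear scale and the arrays were brought to a like median, but how the authors did this is not stated, and it served only as an alternative.

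Of 43602 spots that were not controls, 45 to 135 outlier spots per array were left out, and 1 saturated spot was kept. The processed signal was set to log2, the 75th percentile of each array was subtracted, and spots of 1 probe were averaged, giving 32162 probes. Gene names came from matching each probe's accession or name to a reference gene table of the Release 6 assembly, used for names only: 17544 probes matched by accession, 463 by locus tag, 3624 by symbol and 423 by synonym, 101 kept the name in the file, and 10007 probes had no gene. The brightest probe stood for each of 13267 genes. Genes were tested where this probe was well above background on all 3 arrays of at least 1 group, which left 8472.

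Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 18 arrays (lmFit, then eBayes with default settings, 12 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. Genes were called at an adjusted p under 0.05, and "changed", "rose" and "fell" are used for called genes only. The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. All adjusted p-values of single genes come from limma. The comparisons were PGRP-LC against empty vector in each knockdown, each knockdown against dsGFP with each vector, dsAkirin against dsRelish with PGRP-LC, and the differences of the PGRP-LC effect between dsRelish or dsAkirin and dsGFP. Genes induced by PGRP-LC were those called higher in dsGFP cells by a log2 difference of at least 1. The rule for named genes allowed Rel, akirin and PGRP-LC, the 12 called genes with the largest positive and the 12 with the largest negative difference in each comparison among those whose 3 arrays of one group all lay above the 3 of the other, and members of the gene lists. Genes of the induced set named in other comparisons were picked after their values were seen, and so was the split of genes by whether they could be read in dsRelish cells, which means well above background on all 3 arrays of both dsRelish groups. Bounds in place of differences were first set for genes well above background on no array of a group, and extended to genes on 1 array after the values were seen.

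Shifts of 21 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes in all 10 comparisons, 210 tests adjusted together, of which 57 passed. With an estimated correlation 4 of them passed, namely antimicrobial peptides in dsRelish against dsGFP cells with both vectors, negative regulators in the PGRP-LC cells and the antiviral list in the empty-vector cells, and fry, which tests a list without reference to other genes, called 51. The lists, with members measured, were antimicrobial peptides (14), IMD pathway components (16), IMD negative regulators (13), Toll pathway and Bomanins (17), JNK pathway and targets (15), JAK-STAT pathway and targets (17), SWI/SNF (Brahma) complex (11), phagocytosis and plasmatocyte genes (18), crystal cell and lamellocyte markers (6), fat body markers (3), neuronal and muscle markers (6), heat shock genes (17), apoptosis genes (12), DNA replication and cell cycle (38), ribosome biogenesis (14), RNA interference and antiviral (11), unfolded protein response (19), glycolysis (13), cuticle and ecdysone response (13), ribosomal proteins (83) and glutathione S-transferases (32). Counts of list members are over all genes tested unless they are said to be adjusted over the list alone.

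The arrays lay on 6 slides scanned on 3 days. Scan day 3 held only dsAkirin empty-vector replicates 1 and 2. Deviations from the group means were correlated between same-numbered arrays of the 5 groups other than dsAkirin empty-vector (r across genes between 0.358 and 0.825), so the replicate numbers pair those groups, while r lay between -0.216 and 0.191 for pairs with a dsAkirin empty-vector array. The replicate block named beside results is therefore a fit without that group, chosen after seeing the data, as were the scan day as a block, scan day 2 alone and the fits without the arrays of scan day 3. Alternatives set beforehand were the replicate block on all arrays, the slide as a fixed or a random block (duplicateCorrelation), arrayWeights, normexp background correction with an offset of 50, a median shift, quantile normalization, the series matrix values, other filters on dim probes, outlier spots kept, the mean of all probes of a gene, eBayes with trend and robust, stricter thresholds, fits of only the groups compared, and leaving out each array. Relative to the 75th percentile, the median shift moved the median of all genes by between -0.33 and 0.30 log2, depending on the comparison.

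The fit was tested on simulated data for 8461 genes with the spread of these arrays and 200 genes changed. For the PGRP-LC effect in dsGFP cells it recovered 72.5%, 93.5% and 95.5% of genes changed by a log2 of 1, 2 and 3. For the difference of the PGRP-LC effect it recovered 50.5%, 82.5% and 92.5% in dsRelish and 53.0%, 86.0% and 94.5% in dsAkirin cells. No simulated change was called in the wrong direction. The changed genes were drawn at random from all genes, and every array was drawn independently, without the pairing by replicate number. These shares are therefore averages over genes, and genes with a larger spread are recovered less often. In the data, the replicate block called 110 genes higher by at least 1 log2 in dsGFP cells, and this fit called 12 of them. In 1 further simulated data set, a list of 17 genes was shifted by 0.5 in dsGFP PGRP-LC cells. Camera called it in all 5 comparisons that use this group, which are not separate trials, and 0 of 205 other tests passed. Genes were simulated as independent of each other, so this cannot show how often camera calls correlated lists falsely. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.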

Results

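Gene expression was measured in Drosophila S2 cells, a macrophage-like line derived from embryos, to ask which genes respond to the IMD pathway and which of those responses need Relish or Akirin. The IMD pathway is an innate immune signalling route that starts at the membrane receptor PGRP-LC and ends at Relish, the NF-kappaB factor that switches on antimicrobial peptide genes. Akirin is a nuclear protein known to work with NF-kappaB factors and with the Brahma chromatin remodelling complex at part of their target genes. Cells received double-stranded RNA against GFP, a control sequence that the cells lack, against Relish or against Akirin. In the same transfection they received either a vector expressing PGRP-LCa or the empty vector, and a Tomato fluorescent protein by which transfected cells were sorted. The 6 combinations were measured on 3 arrays each, 18 arrays in all, with 1 sample labelled in 1 colour on each array. The 75th percentile of the signal ranged from 1145.5 to 2351.8 across arrays, and between 45.05% and 65.43% of the probes lay well above background. This percentile, by which the arrays were scaled, differed with the knockdown. It lay between 1535.9 and 2351.8 on dsAkirin arrays, 1145.5 and 1590.7 on dsGFP arrays, and 1208.1 and 1694.2 on dsRelish arrays. The shares of higher and lower genes in dsAkirin cells therefore depend on the scaling. The number of arrays limits precision. Of the 13267 genes on the array, 8472 were well above background on every array of at least 1 group and were tested. The labels number the replicates but do not say that these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

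Relish RNA was almost removed by its double-stranded RNA. The brightest Rel probe (FBgn0014018, chromosome 3R, 4869910 to 4869969 in the dm3 build) stood at 5.29 ± 0.49 (SD, n = 3) on the log2 scale relative to the array's 75th percentile in dsGFP empty-vector cells and at -0.13 ± 0.19 (SD, n = 3) in dsRelish empty-vector cells. This was a 42.8-fold reduction, and with the PGRP-LC vector the reduction was 50.8-fold. Across the 6 dsRelish arrays the probe lay between -0.40 and 0.07, whereas the lowest value on any other array was 4.77. The other Rel probes (3 in all, each above background on all 18 arrays) fell by 5.22 to 5.60 on the log2 scale. Akirin RNA, read by a single probe (FBgn0082598, chromosome 3L, 7365768 to 7365827), was at 4.23 ± 0.11 (SD, n = 3) in dsGFP PGRP-LC cells and at 0.66 ± 0.10 (SD, n = 3) in dsAkirin PGRP-LC cells, an 11.9-fold reduction. In empty-vector cells akirin was 9.01-fold lower with its double-stranded RNA. The PGRP-LC transgene was seen by only 1 of the 5 PGRP-LC probes (FBgn0035976, chromosome 3L, 9335453 to 9335512), which rose by 3.22 ± 0.19 (SE) in dsGFP, 2.60 ± 0.19 in dsRelish and 3.47 ± 0.19 in dsAkirin cells on the log2 scale (adjusted p over all probes 3.23e-06, 5.29e-05 and 1.20e-06). The other PGRP-LC probes differed by between -0.07 and 0.42 and passed no test, the brightest one included, which stands for the gene in every comparison across genes. All 18 arrays thus carried the knockdown and vector state that their labels give, as far as these probes can show it, since the targeted parts of the transcripts are not given in the sources used here.

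**Figure D1:**
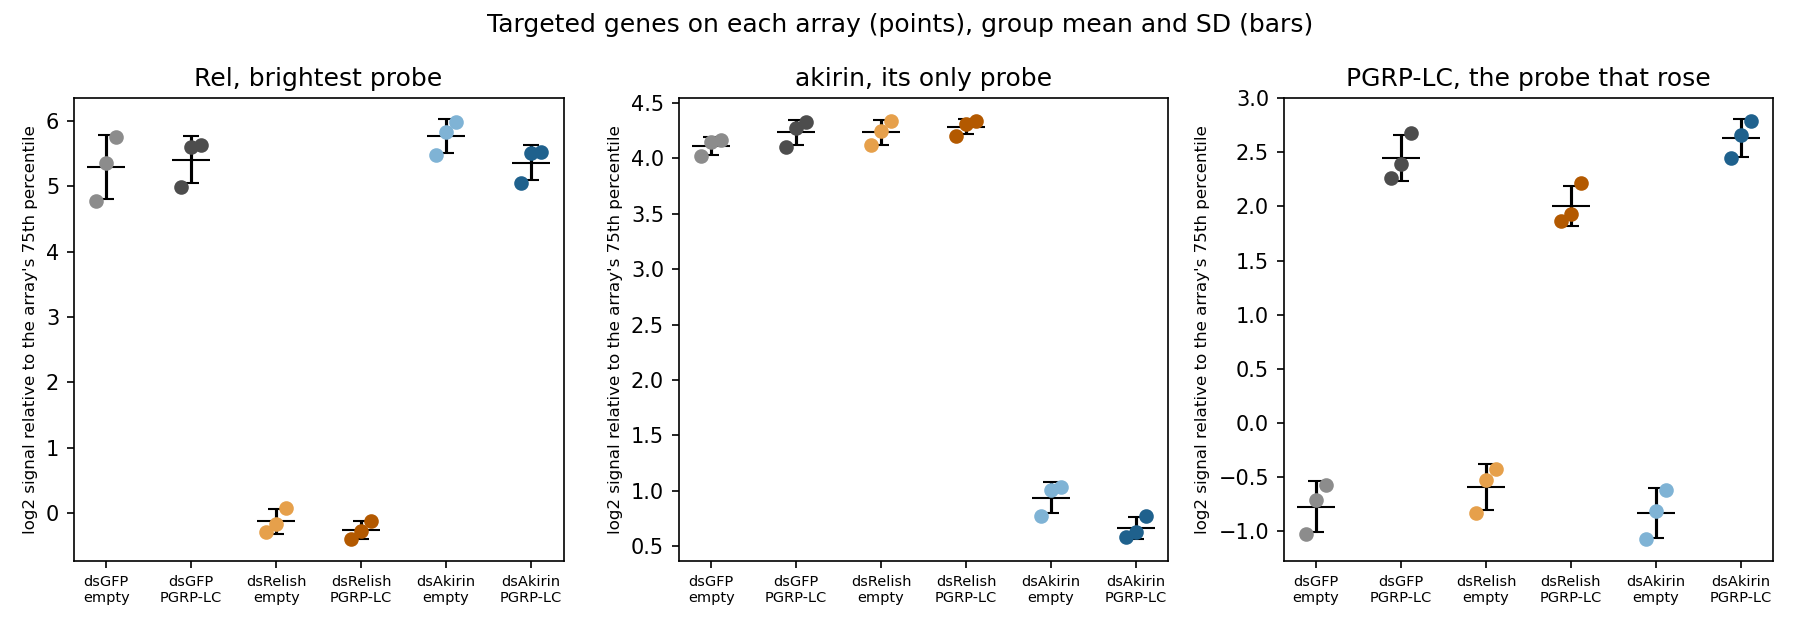
Log2 signal of Rel, akirin and the PGRP-LC probe that rose, relative to each array's 75th percentile, for the 6 groups of cells. Points are the 18 arrays and bars the group mean and SD (n = 3); Rel lies between -0.40 and 0.07 on the 6 dsRelish arrays and at 4.77 or more on every other array.

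In control (dsGFP) cells, the fit without a block called a small group of genes higher with overexpression of PGRP-LC. With the replicate block, the genes called higher by at least 1 log2 grew from 12 to 110. The size of the response therefore depends on the fit, and the values that follow are those without the block. The strongest were CG7296 (log2 difference 3.996 ± 0.68, SE), CG8519 (3.85 ± 0.46), spirit, a serine protease of the Toll-activating cascade (3.67 ± 0.49), and CG9733, a predicted serine protease (3.52 ± 0.50). Tg, the transglutaminase that crosslinks clot proteins, rose at least 4.09-fold, and Tsf1, an iron-binding transferrin of the haemolymph, by 2.15 ± 0.36 on the log2 scale. The planar polarity gene sano, ltl, CG33225, CG13458 and CG10184 rose too, by 1.32 to 2.31, and so did CG30151. Tg was well above background on 1 dsGFP empty-vector array and CG30151 on none, so that their rises are only bounds, of at least 4.57-fold for CG30151. Such bounds, given here and below for genes well above background on at most 1 array of the dimmer group, set the brighter group's mean against, on each array, the higher of the dim probe's own signal and the lowest signal of any probe well above background. They equal the fitted difference where the dim probe's own signal is the higher, and they take no account of the spread between arrays. In all, 18 of 8472 genes changed without the block, 13 of them upward. The 5 that fell were led by rdgA, a diacylglycerol kinase (-3.61 ± 0.39, adjusted p = 7.37e-04), followed by unc-119, a lipid-binding trafficking protein (-1.94), daw, an activin-like ligand (-1.37), Ptth, the prothoracicotropic hormone (-1.11), and BBS4, a ciliary transport gene (at least 2.08-fold). The rdgA fall came from 1 of 9 probes, while the 5 others above background on all 18 arrays lay 0.12 to 0.18 higher.

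Antimicrobial peptide genes lay higher with PGRP-LC in dsGFP cells as a group. All 14 measured members were above 0, with a median log2 difference of 1.22, and AttC (2.66 ± 0.64), DptA (2.07 ± 0.82), Def (2.05 ± 0.80) and AttD (2.03 ± 0.73) were the largest. The group shift passed camera (adjusted p = 5.85e-09), but not with an estimated correlation (adjusted p = 0.276). No single member was called over all genes tested, and 7 were called when adjusted over the list alone. Within the slides that held both vectors, the median was 0.96 on slide 1 and 1.45 on slide 4. Cecropin genes differed less, with CecC at 0.07, CecA2 at 0.18, CecA1 at 0.31 and CecB at 0.42. Negative regulators of the pathway had a median of 0.02, although PGRP-SC2 (2.88 ± 0.65) and PGRP-LB (2.32 ± 0.60) were higher without being called, and Toll pathway genes and Bomanins a median of 0.11, and neither list passed (adjusted p = 0.0981 and 0.139). Counts in this comparison rested on how differences between replicate series were treated: with the replicate number as a block, and without the dsAkirin empty-vector arrays, 414 genes were called, including all 18, and of the antimicrobial peptide genes and negative regulators AttC, Dro, Drs, PGRP-SC1a, PGRP-SC2 and PGRP-LB then passed (adjusted p = 0.0465, 0.0333, 0.0142, 0.0363, 8.23e-04 and 3.48e-04). With the slide as a block 448 genes were called, 74.6% of them higher, and on the arrays of scan day 2 alone 24, there with a single dsGFP empty-vector array that is assumed to vary like the other groups. Of the called genes 72.2% were higher here, against 52.2% with quantile normalization and 50.0% with the median shift. Leaving out dsGFP empty-vector replicate 1, 2 or 3 gave 43, 7 and 7 genes, leaving out dsGFP PGRP-LC replicate 1, 2 or 3 gave 9, 10 and 9, and leaving out dsAkirin empty-vector replicate 3 gave 33.

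In dsRelish cells, PGRP-LC changed fewer genes, and mostly downward. The effect on antimicrobial peptide genes could be read only in part, since 6 of the 14 (AttC, AttD, DptA, Dro, Mtk and Def) were well above background on at most 1 array of either dsRelish group. The 8 others had a median of 0.22 here and of 0.37 in dsGFP cells, and which members could be read was asked after their values were seen. The 8 called genes were rdgA (-3.61 ± 0.39), unc-119 (-2.15 ± 0.35), Fie (-2.11 ± 0.36), CG9813, MFS3, a predicted membrane transporter (-1.65 ± 0.26), Ugt35C1, Act42A, a cytoplasmic actin (-1.15 ± 0.19), and, as the only one that rose, TRAM, a factor of protein translocation into the endoplasmic reticulum (0.66 ± 0.10). CG9813 and Ugt35C1 were well above background on no dsRelish PGRP-LC array and on only 2 dsRelish empty-vector arrays. Their bounds were at least 3.26-fold and at least 2.70-fold lower, but both are uncertain. Of 34 alternatives, 14 and 15 lost the call, and 1, normexp background correction, turned the direction of both. Most of the other calls were no firmer, though none turned direction. Fie lost its call in 24 of 34 alternatives, and Act42A in 21, unc-119 in 17, MFS3 in 16 and TRAM in 12 of 35. Only rdgA kept its call in nearly all, losing it in 1 of 35. DNA replication and cell cycle genes were slightly higher as a group (median 0.26 over 38 genes, adjusted p = 9.73e-10), though no member was called and the adjusted p was 0.276 with an estimated correlation; within slides 1, 3 and 5 the median was 0.22, 0.24 and 0.27. Ribosomal protein genes were lower as a group (median -0.20, adjusted p = 1.87e-15), again without a called member and with an adjusted p = 0.564 with an estimated correlation; within slides 1, 3 and 5 the median was -0.26, -0.22 and -0.15. The replicate block raised the count from 8 to 172 genes and the slide as a block to 148, both with all 8 among them, of which 40.7% and 39.2% were higher. On the arrays of scan day 2 alone 4 genes were called. The share of higher genes was 12.5% here and 0% with the median shift and with the series matrix values, which called 4 and 2 genes. Leaving out dsRelish empty-vector replicate 1, 2 or 3 gave 1, 4 and 1 genes, dsRelish PGRP-LC replicates 2, 2 and 1, dsGFP PGRP-LC replicates 4, 1 and 3, and dsAkirin PGRP-LC replicates 5, 5 and 3, while leaving out replicate 3 of the empty vector gave 1 for dsGFP and 21 for dsAkirin.

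In dsAkirin cells, 181 genes changed with PGRP-LC, 71 upward and 110 downward. Those that rose most were Cpr47Eb, a cuticle protein gene (4.61 ± 0.80), CG34227 (at least 19.5-fold), CG6733 (at least 20.1-fold), CG12896 (3.90 ± 0.70) and its relative Prx6c (3.80 ± 0.70), both of the peroxiredoxin family. Immune genes among them were DptA, which encodes the antibacterial peptide Diptericin (3.62 ± 0.82, adjusted p = 0.0425), PGRP-SC2, an amidase that degrades peptidoglycan (3.07 ± 0.65), Drsl5, a Drosomycin-like gene (2.97 ± 0.68), and TotB, a stress-induced Turandot gene (2.58 ± 0.45). The genes that fell were again led by rdgA (-3.15 ± 0.39), followed by Calx, a sodium/calcium exchanger (-2.33), DopR, a dopamine receptor (-2.23), and retn (-1.83). Antimicrobial peptide genes were higher as a group (median 1.12 over 14 genes, adjusted p = 5.41e-04), but with an estimated correlation the adjusted p was 0.548, and within slide 5, the only slide with both vectors, the median was 0.26. Heat shock genes, the chaperones of the stress response, showed the largest median of any list (2.36 over 17 genes, adjusted p = 5.60e-07, and adjusted p = 0.504 with an estimated correlation). None of them passed over all genes tested, 13 passed when adjusted over the list alone, and within slide 5 their median was 0.74. Glutathione S-transferase genes had GstD2 (1.57), GstD3 (0.60) and GstD7 (1.24) called higher, and passed as a list (median 0.13, adjusted p = 0.00758, and adjusted p = 0.496 with an estimated correlation; median 0.01 within slide 5). Cuticle and ecdysone response genes and ribosomal proteins passed upward as well (medians 0.46 and 0.15), both lost with an estimated correlation (adjusted p = 0.564 and 0.818), and within slide 5 they had medians of -0.11 and -0.20. This comparison uses the dsAkirin empty-vector arrays, of which replicates 1 and 2 were scanned together on scan day 3 with no other group. Without those arrays 12 genes were called, all of them lower, but this fit sets the single array left in the group, assumed to vary like the other groups, against 3, and a lower count is expected from that alone. With the slide as a block 29 genes were called, of which 20.7% were higher. With the median shift 19.3% of the called genes were higher, against 39.2% here. Leaving out dsAkirin empty-vector replicate 1, 2 or 3 gave 8, 2 and 2799 genes, leaving out dsAkirin PGRP-LC replicate 1, 2 or 3 gave 11, 10 and 118, and leaving out any array of another group gave between 53 and 104. On the first 4 principal components across genes, dsAkirin empty-vector replicates 1 and 2 nearly coincided (41.08 and 41.10, -34.84 and -32.15, -9.67 and -8.81, 27.21 and 27.07). Replicate 3 lay apart (30.69, -10.32, 13.9 and -11.91). The group may therefore hold less independent spread than 3 separate samples, which was not tested.

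**Figure D2:**
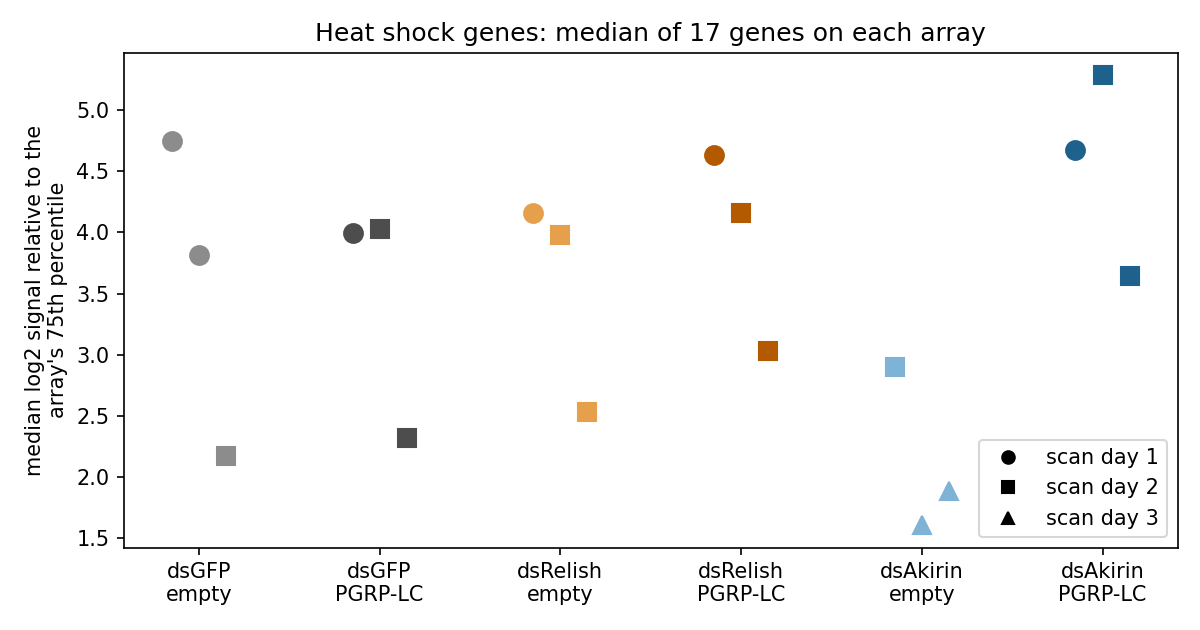
Median log2 signal of the 17 heat shock genes on each of the 18 arrays, relative to the array's 75th percentile, by group. Circles, squares and triangles are scan days 1, 2 and 3; the dsAkirin empty-vector arrays of scan day 3 lie at 1.61 and 1.89, below every other array.

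Relish knockdown strongly lowered the antimicrobial peptide genes in PGRP-LC cells. All 14 measured members fell, with a median log2 difference of -8.68, or -8.40 with 6 of them at their bounds, and 9 of them were among the 12 genes with the largest fitted fall. Mtk, the antifungal peptide Metchnikowin, was at least 2776-fold lower, AttD at least 2654-fold, DptA at least 687-fold, AttC at least 550.0-fold, Dro at least 367-fold and Def at least 258-fold. DptB (-9.99 ± 0.78), AttA (-9.64 ± 0.60) and AttB (-8.29 ± 0.66) fell strongly as well, while CecC fell by 2.28 ± 0.40. The cecropin genes and AttA, AttB, DptB and Drs stayed well above background on all dsRelish arrays, and CecA1 and CecC stood at 1.17 and 0.61 relative to the array's 75th percentile in dsRelish PGRP-LC cells. Nearly identical gene copies, such as AttA and AttB or CecA1 and CecA2, can share signal on an array, so values of single copies are uncertain. The list passed with the preset correlation (adjusted p = 1.67e-55) and with an estimated correlation (adjusted p = 0.00404), and within slides 1 and 3 the median was -9.23 and -8.04. Other secreted immune genes fell with them, namely edin, which is induced by infection (-10.15 ± 0.42), and CG10332, at least 600-fold.

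Some genes that restrain the IMD pathway also fell with Relish knockdown. Among 13 measured negative regulators, 4 were called, all lower: PGRP-LB, an amidase that removes peptidoglycan (at least 501-fold), pirk, which binds PGRP-LC and blocks signalling (-5.96 ± 0.23), PGRP-SC2 (-5.55 ± 0.65) and PGRP-LF (-2.29 ± 0.23). The list passed with the preset correlation (adjusted p = 2.32e-05) and with an estimated correlation (adjusted p = 0.0491), although its median was only -0.11, and -0.04 and -0.17 within slides 1 and 3. From the Toll pathway, the recognition proteins PGRP-SD (-5.98 ± 0.40) and PGRP-SA (-3.09 ± 0.20) and the inhibitor cact (-1.33 ± 0.19) fell (list adjusted p = 0.0179, with a median of only -0.04, and adjusted p = 0.624 with an estimated correlation and 0.0654 with the replicate block; medians -0.02 and -0.14 within slides 1 and 3). In the RNA interference and antiviral list, Sting, a sensor of cyclic dinucleotides (-2.13 ± 0.19), AGO2 (-0.54 ± 0.07) and Dcr-1 (-0.47 ± 0.06) fell (list median -0.16, adjusted p = 9.31e-04, and adjusted p = 0.0693 with an estimated correlation; medians -0.10 and -0.17 within slides 1 and 3). Single calls in other lists were the pathway kinase regulator key (-1.05 ± 0.14), the JNK target Gadd45 (-1.23 ± 0.19), the cytokine upd3 (-0.82 ± 0.20) and Dronc, an initiator caspase (-0.56 ± 0.12). Genes that rose with Relish knockdown changed far less. Pka-C3 (2.20 ± 0.39), CG14857 (at least 4.18-fold), NimC4, a receptor for engulfing dead cells (2.02 ± 0.54), and Apoltp, a lipid transfer lipoprotein (1.80 ± 0.32), led them. Of 369 called genes 287 were lower. With the replicate block 1699 genes were called, all 369 among them, and 56.3% were higher, so the excess of lower genes held for the genes called without the block. The slide as a block gave 1420 genes, 53.7% of them higher, and the arrays of scan day 2 alone gave 295; leaving out dsGFP PGRP-LC replicate 1 gave 245.

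**Figure D3:**
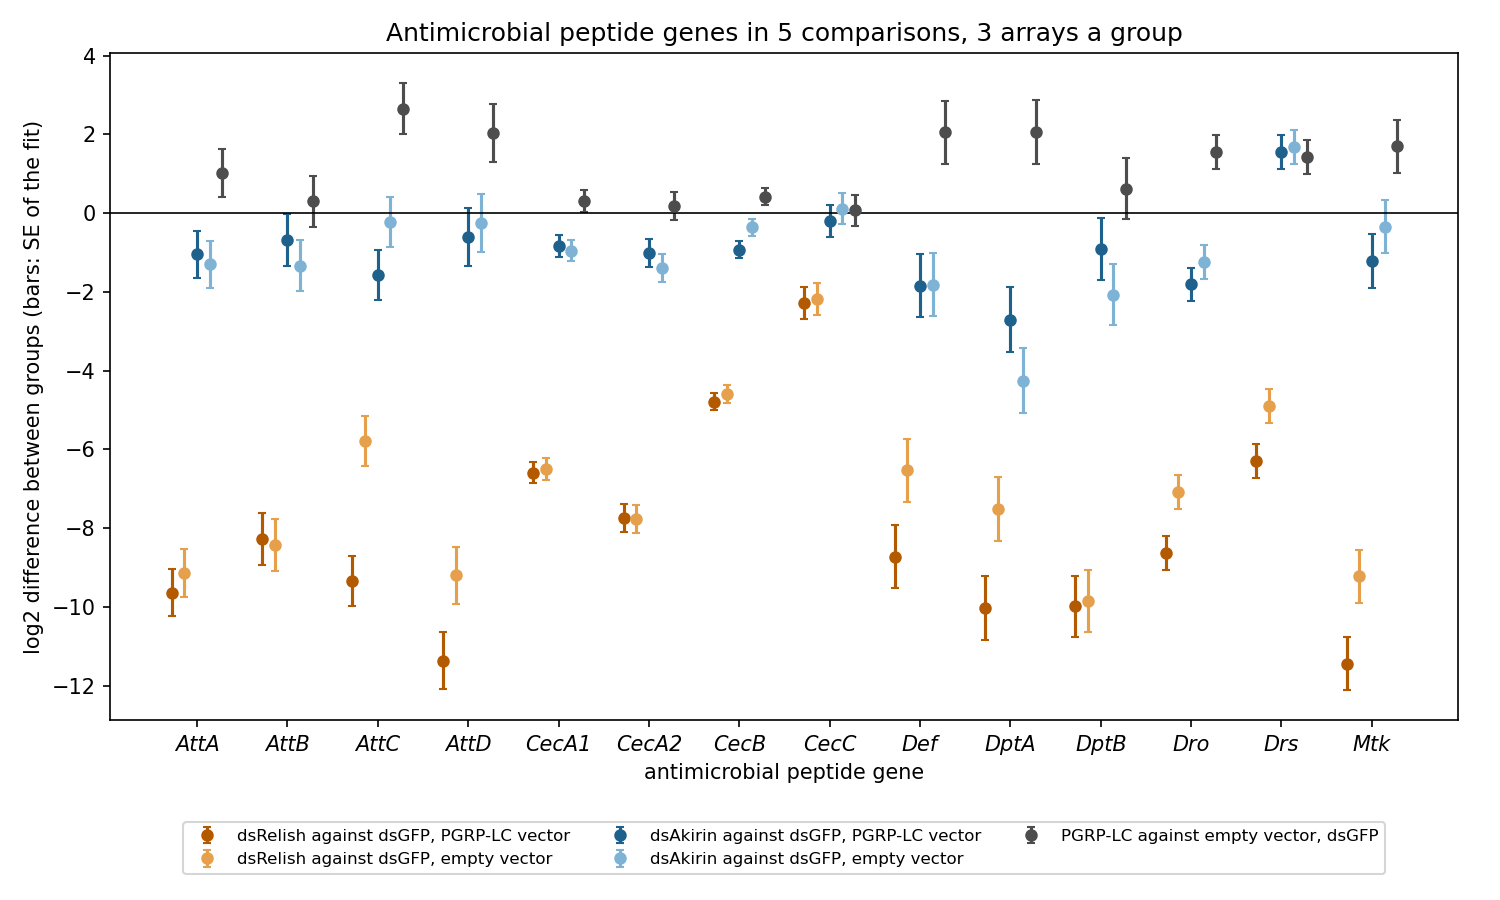
Log2 difference (y axis) of each of the 14 antimicrobial peptide genes (x axis) in 5 comparisons, with the SE of the fit as bars, 3 arrays a group. The dsRelish values lie at -2.18 or lower for every gene, while the dsAkirin values lie between -4.25 and 1.68; values of probes below background on all arrays of a group are not bounds here.

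The same immune genes depended on Relish in cells that had received only the empty vector. All 14 antimicrobial peptide genes fell, with a median of -7.30, or -6.96 with 6 at their bounds (adjusted p = 4.02e-69, and adjusted p = 0.00271 with an estimated correlation; median -7.35 within slide 1). DptB (-9.85 ± 0.78), AttA (-9.14 ± 0.60), Mtk (at least 493-fold) and AttD (at least 454-fold) fell strongly, and DptA (at least 144-fold), Dro (at least 107.3-fold) and Def (at least 57.2-fold) were not well above background on any dsRelish empty-vector array. The infection-induced gene edin (-8.53 ± 0.42), PGRP-LB (at least 69.5-fold), pirk (-5.33 ± 0.23), PGRP-SD (-4.58 ± 0.40), PGRP-SC2 (-3.04 ± 0.65) and PGRP-SA (-2.73 ± 0.20) fell too. Sting (-2.24 ± 0.19), pst (-1.37 ± 0.29), AGO2 (-0.39 ± 0.07) and Dcr-1 (-0.36 ± 0.06) were lower within the RNA interference and antiviral list, which passed with the preset correlation (adjusted p = 2.51e-04) and an estimated correlation (adjusted p = 0.0491; median -0.10, and -0.19 within slide 1). Only 20 genes rose, among them CG14857 (at least 4.35-fold), Apoltp (1.37 ± 0.32) and DOR (1.00 ± 0.18). In total 159 genes were called, 139 of them lower. Both vectors shared 134 genes called lower and 12 called higher with Relish knockdown. This share rests on separate arrays, but not on independent ones. Same-numbered arrays of the vectors were correlated in their deviations from the group means, with r of 0.741 for dsGFP and 0.825 for dsRelish replicate 1. The replicate block called 694 genes (all 159 among them, 40.9% higher), the slide as a block 584 (50.9% higher) and scan day 2 alone, with a single dsGFP array, 76; without dsGFP empty-vector replicate 1 the count was 105.

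Akirin knockdown changed many more genes than Relish knockdown, but moved the antimicrobial peptides much less. In PGRP-LC cells 2335 genes were called, 1051 higher and 1284 lower. Of the 14 antimicrobial peptide genes 5 fell, namely DptA (-2.70 ± 0.82), Dro (-1.81 ± 0.43), CecA2 (-1.02 ± 0.35), CecB (-0.93 ± 0.22) and CecA1 (-0.83 ± 0.27), while Drs, the antifungal peptide Drosomycin, rose by 1.55 ± 0.43. The remaining 8 were not called, and the list as a whole, with a median of -0.97, did not pass (adjusted p = 0.0557; median -1.12 within slide 3). Among regulators pirk (-0.87 ± 0.23) and the adaptor imd (-0.57 ± 0.13) fell, and trbd, a deubiquitinase that limits the pathway (0.64 ± 0.13), and casp (0.24 ± 0.07) rose. Large rises outside immunity included obst-J, a chitin-binding gene (at least 33.8-fold), the digestive amylases Amy-p (at least 35.4-fold) and Amy-d (4.97 ± 0.55), the muscle actin Act79B (at least 21.2-fold), Apoltp (4.26 ± 0.32) and Mlc2, a muscle myosin light chain (3.82 ± 0.20). Obp56h, an odorant-binding protein gene, rose at least 16.1-fold. Of the fat body list 2 of 3 measured members, Apoltp and the yolk protein gene Yp3 (0.61 ± 0.20), rose (list median 0.62, adjusted p = 0.0232, and adjusted p = 0.228 with an estimated correlation and 0.0597 with the replicate block; median 1.21 within slide 3). JAK-STAT targets were higher as a group (median 0.65 over 17 genes, adjusted p = 0.0199, and adjusted p = 0.285 with an estimated correlation; median 0.80 within slide 3), with 6 called higher, including Tep1 (at least 10.0-fold), TotM (2.44 ± 0.47) and TotB (at least 5.78-fold), and 2 lower, dome (-0.43 ± 0.14) and vir-1 (-0.81 ± 0.16).

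Some genes of DNA replication, ribosome biogenesis and the unfolded protein response fell with Akirin knockdown. DNA replication and cell cycle genes had 13 of 38 members called lower and none higher (median -0.34, adjusted p = 2.51e-04, and adjusted p = 0.563 with an estimated correlation; median -0.35 within slide 3). Members included the helicase subunits Mcm6 (-0.85 ± 0.14) and Mcm7 (-0.84 ± 0.16), the licensing factor dup (-0.82 ± 0.17) and the ribonucleotide reductase RnrS (-0.87 ± 0.22). Ribosome biogenesis genes had 10 of 14 called lower and only Non1 called higher (median -0.50, adjusted p = 2.51e-04, and adjusted p = 0.228 with an estimated correlation; median -0.51 within slide 3), with mbm (-0.83 ± 0.11) and pit (-0.77 ± 0.09) at the front. Unfolded protein response genes had 9 of 19 called lower, such as the translocon subunit Sec61beta (-0.98 ± 0.13) and the factor Xbp1 (-0.52 ± 0.09), and none higher (median -0.40, adjusted p = 0.00350, and adjusted p = 0.276 with an estimated correlation; median -0.37 within slide 3). Components of the SWI/SNF (Brahma) complex, the remodeller that works with Akirin, did not pass as a list (median -0.19, adjusted p = 0.0543, and adjusted p = 0.0388 with the replicate block; median -0.15 within slide 3), and 2 of 11, Bap111 (-0.34 ± 0.08) and polybromo (-0.31 ± 0.09), were lower. Outside the lists the falls included eg, a transcription factor (at least 6.33-fold), Ipo9, an importin (-2.71 ± 0.23), the cuticle gene Cpr67Fa1 (at least 5.85-fold) and Nazo, an antiviral factor downstream of Sting (-2.12 ± 0.11). The replicate block called 4865 genes, all 2335 among them, the slide as a block 4436 and scan day 2 alone 2239. Without dsAkirin PGRP-LC replicate 2 the count was 1470, with quantile normalization 60.3% and with the series matrix values 58.1% of the called genes were higher, against 45.0% here.

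Many of the genes changed by Akirin knockdown with PGRP-LC also changed in empty-vector cells. Amy-p (at least 18.4-fold), Amy-d (at least 18.9-fold), Apoltp (4.56 ± 0.32), Mlc2 (4.32 ± 0.20), atk, a leucine-rich repeat gene (at least 19.0-fold), Prosbeta2R2, a proteasome subunit gene (at least 15.8-fold), and Tdh, the threonine dehydrogenase (4.68 ± 0.69), rose. DptA showed the largest fitted fall of all (-4.25 ± 0.82), CecA2 (-1.39 ± 0.35), Dro (-1.24 ± 0.43) and CecA1 (-0.95 ± 0.27) fell, and Drs again rose (1.68 ± 0.43), with a list median of -1.10 that did not pass (adjusted p = 0.0800). GstE4 (at least 12.7-fold), DCTN4-p62, a dynactin subunit (-2.48 ± 0.30), abd-A, a homeotic gene (-2.44 ± 0.54), and Ipo9 (-2.41 ± 0.23) fell as well. Among phagocytosis and plasmatocyte genes the engulfment receptors Sr-CI (2.75 ± 0.55), NimC4 (2.22 ± 0.54), NimC1 (at least 4.39-fold) and eater (1.76 ± 0.51) rose and the collagen gene Col4a1 (-0.67 ± 0.21, but 0.01 with the arrays of scan day 3 left out, which leaves 1 array) fell, in a list that did not pass (median 0.98 over 18 genes, adjusted p = 0.249). Of 12 apoptosis genes 4 rose, among them the Bcl-2 family gene Buffy (at least 6.79-fold) and Dronc (0.58 ± 0.12), without a list shift (median 0.30, adjusted p = 0.0803). Ribosome biogenesis genes (7 of 14 lower, median -0.41, adjusted p = 0.00227) and DNA replication and cell cycle genes (13 of 38 lower, median -0.20, adjusted p = 0.0205) were lower, lost with an estimated correlation (adjusted p = 0.276 and 0.716). Ribosomal protein genes had 59 of 83 members called lower (median -0.58, adjusted p = 1.69e-11), but the adjusted p was 0.616 with an estimated correlation, and with quantile normalization or the series matrix values the list turned to medians of 0.03 and 0.04. Heat shock genes were lower as a group (median -1.40, adjusted p = 0.0386, and adjusted p = 0.794 with an estimated correlation), with Hsp83 called (-1.02 ± 0.18). The list turned direction in 2 of 12 alternatives, the slide and the scan day as a block. On scan day 2 its median signal was 2.90 on the dsAkirin array and 2.18 on the dsGFP array, whereas the dsAkirin arrays of scan day 3 stood at 1.61 and 1.89. In all 2964 genes were called, 1497 higher and 1467 lower, and 791 higher and 774 lower were shared with PGRP-LC cells. No slide held both of these groups; without the 2 dsAkirin arrays of scan day 3, which leaves 1 dsAkirin array against 3, the count was 950, and with scan day 2 alone, which sets 1 array against 1, it was 246, in both with the spread taken from the other groups. Without dsAkirin empty-vector replicate 1 the count was 1837, without replicate 2 it was 1863 and without replicate 3 it was 3693. Replicates 1 and 2 nearly coincided on the principal components given above, so the spread within this group may be understated. The share of higher genes was 63.2% with quantile normalization, 63.1% with the series matrix values and 66.5% with the median shift, against 50.5% here.

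The dsAkirin and dsRelish cells with PGRP-LC were also set against each other, since both carried the receptor. All 14 antimicrobial peptide genes were higher in dsAkirin cells, with a median of 7.46, or 7.13 with 6 at their bounds (adjusted p = 1.79e-18, and adjusted p = 0.103 with an estimated correlation; medians 6.63 and 7.08 within slides 3 and 5). AttD was at least 1742-fold and Mtk at least 1195-fold higher, edin was higher by 9.64 ± 0.42, Drs by 7.85 ± 0.43 and Obp99a, an odorant-binding protein gene, at least 384-fold. Genes lower in dsAkirin cells included Ipo9 (-2.74 ± 0.23), GstE4 (at least 5.92-fold), Agpat2, an enzyme of phospholipid synthesis (-2.16 ± 0.23), and the vesicle transporter gene Vmat (-2.06 ± 0.45). The Brahma complex had 7 of 11 components called lower, such as the ATPase brm (-0.39 ± 0.10) and Snr1 (-0.42 ± 0.09), with a median of -0.39 (adjusted p = 0.00622, and adjusted p = 0.170 with an estimated correlation; medians -0.36 and -0.32 within slides 3 and 5). Part of this may come from dsRelish cells, where the list was higher than in dsGFP cells with PGRP-LC (median 0.17, camera adjusted p = 0.0477) with no member called. That adjusted p was 0.276 with an estimated correlation and 0.0678 with the replicate block, and 11 of 12 alternatives lost the call but kept the direction. Within slides 1 and 3 the medians were 0.19 and 0.21. In this comparison 3122 genes were called, 1259 higher and 1863 lower. The replicate block called 5326 genes, 3121 of them shared, the slide as a block 5156 and scan day 2 alone 3040. With the median shift 19.4% of the called genes were higher, against 40.3% here.

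Whether the response to PGRP-LC itself differed between knockdowns was tested as a difference of differences. In dsRelish against dsGFP cells 2 genes passed, CG8519 (adjusted p = 0.0260) and CG13458 (adjusted p = 0.00643), both raised by PGRP-LC in control cells. Neither could be read in dsRelish cells, where CG13458 was well above background on no array and CG8519 on 1, so these tests set the rise in dsGFP cells against background signal, and the size of the difference is not known. The antimicrobial peptide list was lower in this difference (median -0.95, adjusted p = 1.35e-06, and adjusted p = 0.346 with an estimated correlation; median -1.57 within slide 1). Over the 8 members that could be read in dsRelish cells the median was -0.12, but these had risen little in dsGFP cells (median 0.37, against 2.04 for the 6 others). Of those 8 the largest effect in dsGFP cells was that of Drs, at 1.43 there and 0.03 in dsRelish cells, a difference that was not called. For the 6 others a smaller response cannot be told from signal lost in background. In dsAkirin against dsGFP cells limma called 0 genes, with 797 at an unadjusted p under 0.05, and the antimicrobial peptide list did not pass (median -0.08, adjusted p = 0.936). On scan day 2 alone, with 1 empty-vector array in each of these knockdowns, the median was -1.17, and within slides the PGRP-LC effect had a median of 0.26 in dsAkirin cells (slide 5) against 0.96 and 1.45 in dsGFP cells (slides 1 and 4), so a smaller response is not excluded. For Akirin the count was 0 with the slide or the replicate number as a block, and 1832 with arrayWeights; leaving out dsAkirin empty-vector replicate 3 gave 1367. For Relish the replicate block called 53 genes (13.2% higher), of which 28 were well above background on all arrays of both dsRelish groups (median -0.84), and the slide as a block 33, while leaving out any single array left between 1 and 4.

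The genes induced by PGRP-LC in control cells were followed through the other knockdowns. This set held the 12 genes called higher by a log2 difference of at least 1, with a median of 2.35 in dsGFP cells, the arrays on which they were chosen. In dsRelish cells, which played no part in the choice, their median PGRP-LC effect was -0.24, but 9 of the 12 were not well above background on all arrays of both dsRelish groups, so that their effect cannot be read there. The 3 others, CG10184, sano and Tsf1, stood at 0.43, -0.24 and -0.24, against 1.32, 2.31 and 2.15 in dsGFP cells. In dsAkirin cells it was 1.42, with all 12 above 0, and Tsf1 (2.02), Tg (1.76) and spirit (2.02) among those called there. Without the dsAkirin empty-vector arrays of scan day 3 the 3 genes stood at 0.99, 1.62 and 1.56, none called, in a fit with 1 array left in that group, where calls are lost through the smaller number of arrays as well. The median in dsAkirin cells was 1.02 within slide 5 and 0.92 within scan day 2. Under PGRP-LC, all 12 were lower in dsRelish than in dsGFP cells, although this comparison shares the dsGFP arrays that chose the set. In dsAkirin cells 5 of them were lower than in dsGFP cells, including spirit (-2.28 ± 0.49), CG7296 (-2.64 ± 0.68) and CG8519 (-2.39 ± 0.46), and 4 were higher, including CG13458 (3.61 ± 0.21), Tg (1.47 ± 0.40) and Tsf1 (1.04 ± 0.36). The other 3 were not called, and the 95% interval of the difference was -0.47 to 0.14 for CG10184, -1.32 to 0.48 for CG30151 and -0.84 to 0.77 for sano. With the replicate block, and without the dsAkirin empty-vector arrays, the set grew to 110 genes that included these 12, with 30 called lower in the difference of differences. That count is biased towards lower, since the difference subtracts the dsGFP effect by which the set was chosen. Of these 110, 38 could be read on all arrays of both dsRelish groups. Their median was 0.21 there and 1.31 in dsGFP cells, where the choice itself favours high values. Leaving out dsGFP empty-vector replicate 1, 2 or 3 gave sets of 19, 5 and 5 genes and leaving out dsGFP PGRP-LC replicate 1 or 3 gave 7.

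**Figure D4:**
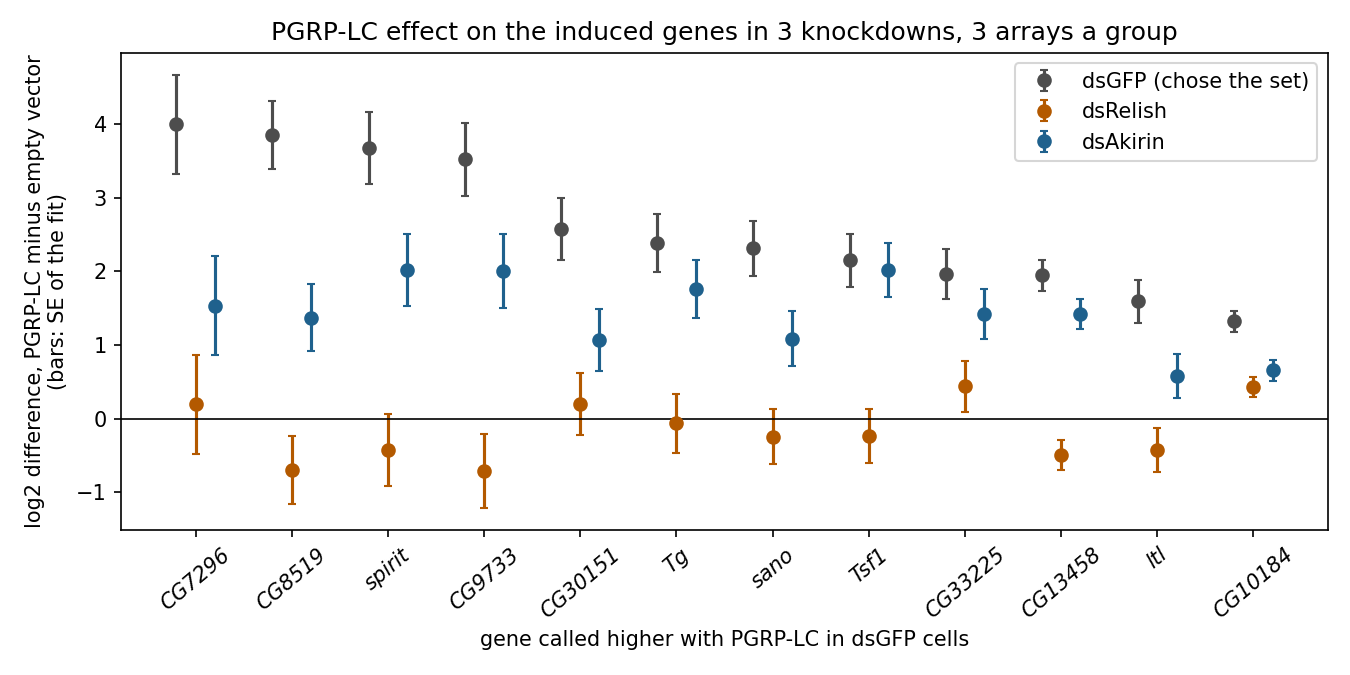
Log2 difference between PGRP-LC and empty-vector cells (y axis) for the 12 genes called higher in dsGFP cells (x axis), in the 3 knockdowns, with the SE of the fit as bars (3 arrays a group). Values in dsAkirin cells are all above 0, with a median of 1.42, and values in dsRelish cells have a median of -0.24, with 9 of the 12 not well above background on all dsRelish arrays.

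Some genes were called with both Relish and Akirin knockdown. In PGRP-LC cells 90 genes were called in the same direction in both, 33 higher and 57 lower, and 47 in opposite directions. The shared falls included DptA, Dro, CecA1, CecA2, CecB, pirk and Sting, and the shared rises Apoltp and NimC4. Independent lists of these sizes would share 53.7 genes, 10.2 higher and 43.5 lower. With only 3 control arrays no split of the controls was made, so part of the excess may come from the shared controls. The covariance of the fold changes across 8472 genes was 0.0539. In 100 simulations of unchanged groups that shared simulated control arrays it was 0.0439, a difference of 0.00998. The correlation across genes, which are not independent replicates, was 0.119, against a simulated 0.50. The simulations drew every array independently from the spread around the group means. Same-numbered arrays of these groups were correlated, and what they share cancels between knockdown and control. The simulated values may therefore be too high, and no conclusion on shared effects is drawn from them. The overlap of dsRelish and dsAkirin calls in PGRP-LC cells was 566 with the replicate block, 465 with the slide as a block and 82 with scan day 2 alone; without dsGFP PGRP-LC replicate 1 or 3 the count was 43 and 51, and without dsAkirin PGRP-LC replicate 2 it was 47.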

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

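The tests of the antimicrobial peptide genes, of the other rdgA probes, of which genes lay above background in dsRelish cells and of the splits that keep the replicate pairing were chosen only after the result was seen, while those of the heat shock genes and the remaining splits of the samples were set beforehand.

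The response to PGRP-LC differed between dsRelish and dsGFP cells for 2 genes, CG13458 (fitted -2.44) and CG8519 (fitted -4.55), and for 6 gene lists in the test of the difference itself. Both genes lay in background in dsRelish cells, so their fitted values do not measure a response there. With the replicate block 53 genes were called, of which 28 could be read in dsRelish cells, with a median difference of -0.84. These lists were antimicrobial peptides (median -0.95), IMD negative regulators (-0.16, adjusted p = 0.00952, and 0.228 with an estimated correlation), crystal cell and lamellocyte markers (-0.31, adjusted p = 0.0239, and 0.228 with an estimated correlation), the SWI/SNF (Brahma) complex (0.12, adjusted p = 0.0408, and 0.276 with an estimated correlation and 0.0631 with the replicate block), DNA replication and cell cycle genes (0.23, adjusted p = 1.16e-05, and 0.496 with an estimated correlation) and ribosomal proteins (-0.13, adjusted p = 3.91e-04, and 0.815 with an estimated correlation). Over the members well above background on all arrays of both dsRelish groups the median was -0.12 for 8 antimicrobial peptides and -0.12 for 11 negative regulators, while the 6 and 2 others had fitted medians of -2.21 and -2.59, so these list shifts rest mainly on genes whose response cannot be read in dsRelish cells. Of the 8, Drs had the lowest difference (-1.40, not called). Between dsAkirin and dsGFP cells the lists that differed were heat shock genes (median 2.26, adjusted p = 3.62e-08), cuticle and ecdysone response genes (0.60, adjusted p = 2.96e-04) and ribosomal proteins (0.24, adjusted p = 6.45e-08), with 0.496, 0.496 and 0.713 with an estimated correlation. The cuticle list turned direction in 2 and ribosomal proteins in 3 of 12 alternatives, among them the slide as a block and the fit without the arrays of scan day 3. Within slide 1, which held both vectors of dsRelish and dsGFP, the medians were -1.57 for antimicrobial peptides, -0.28 for negative regulators, -0.38 for the crystal cell list, 0.15 for the Brahma complex, 0.29 for cell cycle genes and -0.14 for ribosomal proteins. Ribosomal proteins turned direction in this dsRelish difference in 2 of 12 alternatives, quantile normalization and the series matrix values. No slide held all 4 groups of the Akirin difference.

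Heat shock genes were 2.36 higher with PGRP-LC in dsAkirin cells, and per-array medians placed the dsAkirin empty-vector arrays at 1.61, 1.89 and 2.90 and the dsAkirin PGRP-LC arrays at 4.68, 5.28 and 3.64. A candidate technical explanation is that the 2 empty-vector arrays of scan day 3 stand apart from the third. If it were the whole cause, slide 5, which holds the third with its PGRP-LC partner, was predicted to lose most of the shift, and otherwise to keep most of it; its median of 0.74 lay between the 2 bounds set for these outcomes. The biological explanation, that Akirin knockdown changes this response, needed a difference from dsGFP cells without those arrays, and it was 1.73, but within replicate series 3 it was 0.50. Series 3 also stood lowest in each dsGFP and dsRelish group. In dsGFP cells it stood at 2.18 against 4.75 and 3.82 with empty vector, and at 2.32 against 3.99 and 4.03 with PGRP-LC. The fit behind the 1.73 sets a lone dsAkirin array of series 3 against 3 series, so it holds this difference too. A difference of the arrays of scan day 3, a difference between replicate series and an effect of Akirin cannot be told apart here. The reason is that 1 array is all that the dsAkirin empty-vector group has on another day.

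Antimicrobial peptide genes were higher as a list with PGRP-LC in dsGFP cells, yet none was called. Flagged saturation hiding a rise is argued against, since 0 spots of their 23 probes were flagged as saturated on the dsGFP arrays. That flag cannot show a flattening of bright spots below saturation, which was not tested. Differences between replicate series may hide single members, since with the replicate block 3 of them passed, AttC (2.66, adjusted p = 0.0465), Dro (1.54, adjusted p = 0.0333) and Drs (1.43, adjusted p = 0.0142). The dependence of the response on the PGRP-LC dose was not tested.

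The gene rdgA was the only gene called lower with PGRP-LC in all 3 knockdowns, and 0 genes were called higher in all 3. A lower amount of rdgA RNA as a whole is argued against by its 5 other probes above background on all 18 arrays, whose median effect was 0.16, -0.02 and 0.30 in dsGFP, dsRelish and dsAkirin cells, the lowest being -0.0222 with a median SE of 0.15. A difference in 1 transcript form, or in what hybridises to that 1 probe, stays open, and no biological explanation was tested. Among the probes without a gene, 2 fell in all 3 knockdowns in the same way, by -2.86, -3.36 and -3.05 and by -3.66, -4.04 and -3.35.

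Probes without a gene name, which no comparison of genes used, also held signal. Of 3212 such probes well above background in at least 1 group, limma called 3, 4 and 281 in the PGRP-LC effect in dsGFP, dsRelish and dsAkirin cells, 42 and 14 in dsRelish against dsGFP with PGRP-LC and empty vector, 164 and 1131 in dsAkirin against dsGFP with PGRP-LC and empty vector, and 326 in dsAkirin against dsRelish. Of the 1131, 882 were lower in dsAkirin empty-vector cells, and of the 281, 220 were higher with PGRP-LC.

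Other splits of the same arrays were counted for every comparison. With 3 arrays against 3 there are 10 splits, which are too few for a share under 0.05. As many genes as in the real split came from 1 split, the real one, for the PGRP-LC effect in dsGFP cells (18 genes, highest other 1) and dsRelish cells (8, highest other 0), for dsRelish against dsGFP with PGRP-LC (369, highest other 0) and empty vector (159, highest other 0), for dsAkirin against dsGFP with PGRP-LC (2335, highest other 0) and empty vector (2964, highest other 45), and for dsAkirin against dsRelish (3122, highest other 0). For the PGRP-LC effect in dsAkirin cells 2 of 10 splits gave as many as the real 181, and the highest other, which sets dsAkirin empty-vector replicates 1 and 2 and PGRP-LC replicate 1 against the rest, called 1039. That split follows the scan days, so it points to a structure of these samples, and with the scan day as a block 37 genes were called. For the difference of the PGRP-LC effect in dsRelish cells 11 of 100 splits gave at least the real 2 genes, with a highest other of 172. Those splits exchange labels separately in each vector, which can bring the difference between the knockdowns themselves into the count. They therefore cannot decide on chance, which is not excluded. They also ignore the pairing of the replicates, and with the replicate block the real count was 53. When knockdown labels were exchanged only between same-numbered arrays, 4 of 32 splits gave at least the real 53 with that block, with a highest other of 2012. The 3 others among these 4 exchange labels unlike in the vectors, which brings the difference between the knockdowns themselves into the count. The 3 other splits that exchange labels alike in both vectors gave 0 genes with limma, but 4 such splits are too few for a share under 0.05. For dsAkirin cells the real count was 0, so that the splits decide nothing there; the highest other of 100 was 956.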

How the results depend on the processing

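The tests with the scan day as a block, scan day 2 alone, the replicate block without dsAkirin empty-vector arrays and the fits without the arrays of scan day 3 were chosen only after the result was seen. Rel and akirin knockdown kept direction and call under every alternative, with log2 values between -5.87 and -5.19 for Rel and between -3.64 and -3.09 for akirin when any single array was left out, and so did the PGRP-LC probe that rose (2.48 to 3.58), except that the mean of all PGRP-LC probes gave 0.60 in dsRelish cells, not called, since the mean includes the probes that did not rise. Of the alternative values for named genes 5776 kept direction and call, 923 lost the call, 26 gained one and 16 turned direction; of those for gene list shifts 485, 178, 0 and 21 did. DptA in dsAkirin against dsGFP with PGRP-LC lost its call in 4 of 34 alternatives, and CG8519 in the difference for dsRelish in 18 of 34. Some calls were lost more often. In the PGRP-LC effect in dsAkirin cells, DptA lost its call in 22 of 34, spirit in 28 of 34 and GstD2 in 25 of 35. NimC4 in dsRelish against dsGFP with PGRP-LC lost its call in 19 of 35. Outlier spots kept, and fry, moved no count by over 1.5 times. Precision is limited by 3 arrays a group, and genes below background give bounds at most. The cause of the changes in the following values was not tested unless one is given.

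Counts are given in the order PGRP-LC effect in dsGFP, dsRelish and dsAkirin cells, dsRelish and then dsAkirin against dsGFP with PGRP-LC, the same with empty vector, dsAkirin against dsRelish, difference of the PGRP-LC effect for dsRelish, genes in the induced set, and overlap of dsRelish and dsAkirin calls in PGRP-LC cells; those within 1.5 times the reported value are left out by name. An adjusted p under 0.01 gave 7, 1, 8, 211, 1186, 100, 1570, 1907, 1, 5 and 23, as a stricter threshold must give fewer. Asking for at least a 2-fold difference gave 62 for the PGRP-LC effect in dsAkirin cells, 217, 529, 104, 773 and 795 for the knockdowns and 28 for the overlap. Fits of only the groups compared, with fewer arrays for the spread, gave 2, 2 and 0 for the PGRP-LC effects, 186 and 61 for dsRelish against dsGFP, 1218 for dsAkirin against dsGFP with empty vector, 1 for the difference, 0 induced and an overlap of 43. Normexp background correction gave 2, 1, 2, 134, 810, 70, 1348, 1094, 0, 1 and 14, and medians of the induced set of 0.56 in dsRelish and 0.65 in dsAkirin cells. The median shift gave 30 and 4 for the PGRP-LC effects in dsGFP and dsRelish cells, 229 for dsRelish and 1022 for dsAkirin against dsGFP with PGRP-LC, 1641 for dsAkirin with empty vector, 0 for the difference and an overlap of 40. Quantile normalization gave 0 for the difference. The series matrix values gave 2 and 406 in dsRelish and dsAkirin cells and 1 for the difference. No filter on dim probes gave 7, 1 and 22 for the PGRP-LC effects, 1 for the difference, 5 induced and an overlap of 51, and only genes above background on all 18 arrays gave 7, 5 and 332, 0 for the difference and 3 induced. The mean of all probes gave 4 in dsRelish cells, and eBayes with trend and robust gave 338 in dsAkirin cells. ArrayWeights gave 36, 29 and 4516 for the PGRP-LC effects, 4789 for dsAkirin against dsGFP with empty vector, 1832 for the difference of the PGRP-LC effect in dsAkirin cells, 19 induced and an overlap of 142.

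Blocks raised most counts. For the PGRP-LC effect in dsAkirin cells the slide and the scan day as a block lowered the count, while the replicate block on all arrays raised it. The slide as a fixed block gave 448, 148 and 29 for the PGRP-LC effects, 1420, 4436 and 584 for dsRelish and dsAkirin against dsGFP with PGRP-LC and dsRelish with empty vector, 5156 for dsAkirin against dsRelish, 33 for the difference, 135 induced with a median of 0.60 in dsAkirin cells, and an overlap of 465. The slide as a random block gave 487, 155 and 114, then 1516, 4405 and 581, then 5128, 68, 148 with a median of 0.80, and 477. The scan day as a block gave 312, 49 and 37, then 1006, 4056, 432 and, for dsAkirin with empty vector, 1917, then 33, 139 with a median of 0.61, and 305. Scan day 2 alone gave 4 and 2 for the PGRP-LC effects in dsRelish and dsAkirin cells, 76 and 246 for dsRelish and dsAkirin with empty vector, 0 for the difference and a median of 0.74 for the induced set in dsAkirin cells. The replicate block on all arrays, which assumes a pairing that the dsAkirin empty-vector arrays lack, gave 126, 30 and 1451, then 734 and 295 for dsRelish, 4, 61 induced and an overlap of 214. The replicate block without those arrays gave 414 and 172, then 1699, 4865, 694 and 5326, then 53, 110 and 566. Without the 2 dsAkirin empty-vector arrays of scan day 3, 12 genes were called in the PGRP-LC effect in dsAkirin cells and 950 in dsAkirin against dsGFP with empty vector. That fit leaves 1 dsAkirin empty-vector array, and scan day 2 alone leaves 1 empty-vector array each in dsGFP and dsAkirin cells; a lone array is assumed to vary like the other groups, and fewer arrays alone give fewer calls. Among 147 list tests without the dsAkirin empty-vector group, 46 passed with the replicate block against 42 without it. Beside the changes of list calls given with the results, that block ended the calls of glycolysis in dsGFP cells (0.0597), the Toll list in dsRelish against dsGFP with empty vector (0.0976), the Brahma list in dsRelish against dsGFP with PGRP-LC (0.0678) and the antiviral list in dsAkirin against dsRelish (0.0501). It added calls of the unfolded protein response (0.0253) and the cuticle list (0.0121) in dsRelish cells, of phagocytosis genes in dsAkirin against dsGFP (0.0311) and dsRelish (0.0313) with PGRP-LC, and of glutathione S-transferases in the difference for dsRelish (0.0322). Camera with an estimated correlation called 4 list shifts in place of 57, and the other alternatives between 44 and 66.

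Leaving out each array in turn gave between 7 and 43 genes for the PGRP-LC effect in dsGFP cells, 1 and 21 in dsRelish cells and 2 and 2799 in dsAkirin cells, the extremes in dsAkirin cells without dsAkirin empty-vector replicates 2 and 3. It gave between 245 and 503 for dsRelish and 1470 and 2998 for dsAkirin against dsGFP with PGRP-LC, 105 and 192 and 1837 and 3693 with empty vector, and 2294 and 3682 for dsAkirin against dsRelish. The differences of the PGRP-LC effect gave between 1 and 4 for dsRelish and 0 and 1367 for dsAkirin, the induced set held between 5 and 19 genes with medians between -0.49 and -0.04 in dsRelish and 1.17 and 1.67 in dsAkirin cells, and the overlap lay between 43 and 132. Rel lay between -5.87 and -5.55 with PGRP-LC and -5.68 and -5.19 with empty vector, akirin between -3.64 and -3.52 and -3.22 and -3.09, and the PGRP-LC probe between 3.095 and 3.32 in dsGFP, 2.48 and 2.69 in dsRelish and 3.35 and 3.58 in dsAkirin cells. Lists were not tested again without single arrays.

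Directions turned in some list shifts. For the PGRP-LC effect in dsAkirin cells, the cuticle list lay at -0.16, -0.079 and -0.14 and ribosomal proteins at -0.25, -0.29 and -0.32 with the slide as a block, with the scan day as a block and without the arrays of scan day 3, ribosomal proteins at -0.086 with the slide as a random block, and glutathione S-transferases, with a median of 0.020 on the slide block, turned in the test. In the difference of the PGRP-LC effect for dsAkirin, the cuticle list lay at -0.080 and -0.072 with the slide as a block and without the arrays of scan day 3, and ribosomal proteins at -0.14, -0.24 and, with the scan day as a block, -0.19. Heat shock genes in dsAkirin against dsGFP with empty vector lay at 0.22 and 0.13 with the slide and the scan day as a block. Ribosomal proteins lay at 0.054 with quantile normalization and 0.055 with the series matrix values in dsAkirin against dsGFP with PGRP-LC, at 0.033 and 0.039 with empty vector, and at 0.059 and 0.051 in the difference for dsRelish. Among genes, CG9813 (0.27) and Ugt35C1 (0.11) turned with normexp in dsRelish cells, and Col4a1 in dsAkirin against dsGFP with empty vector lay at 0.019 with the scan day as a block and 0.011 without the arrays of scan day 3. Of genes not called, CecC in the PGRP-LC effect in dsGFP cells lay at -0.036 with the median shift, -0.042 with arrayWeights, -0.29 with scan day 2 alone and between -0.31 and 0.36 without single arrays. For sano in dsAkirin against dsGFP with PGRP-LC the mean of all probes gave 0.088, arrayWeights 0.11, scan day 2 alone 0.37 and single arrays left out between -0.27 and 0.42. CG30151 lay there between -0.80 and 0.0996 without single arrays.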

Other observations

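Every list and comparison in this part was set beforehand, while the alternatives without the arrays of scan day 3 and with the scan day as a block were chosen only after the result was seen.

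Lists that no comparison turned on were measured as well. IMD pathway components had key and Rel itself called lower in dsRelish against dsGFP with PGRP-LC (median -0.09 over 16 genes, adjusted p = 6.32e-04, and 0.346 with an estimated correlation; medians -0.07 and -0.11 within slides 1 and 3), a shift that contains the targeted gene. JNK pathway genes and targets did not shift in dsAkirin against dsGFP with PGRP-LC (median -0.10 over 15 genes, 3 called higher and 2 lower, adjusted p = 0.936). Neuronal and muscle markers had a median of -0.11 but a mean of 0.69 there, with 2 of 6 measured genes called higher, Mlc2 among them, and no shift (adjusted p = 0.295). Glycolysis genes were lower in dsAkirin against dsGFP with empty vector, with 5 of 13 called lower (median -0.36, adjusted p = 0.0199, and 0.503 with an estimated correlation). This shift kept its direction but did not pass in 9 of 12 alternatives, among them the fit without the dsAkirin empty-vector arrays of scan day 3, which leaves 1 array in that group (median -0.21, adjusted p = 0.407), and the slide as a block (median -0.08, adjusted p = 0.716). Ribosome biogenesis genes were higher with PGRP-LC in dsRelish cells without a called member (median 0.18, adjusted p = 0.00155, and 0.276 with an estimated correlation; medians 0.13, 0.17 and 0.16 within slides 1, 3 and 5).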
